A study of Homo sapiens with 54 samples.

How the data were processed

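Total RNA and RNA from anti-Argonaute immunoprecipitates (antibody 2A8) of transfected H4 cells was measured on Affymetrix Human Gene 1.0 ST arrays, with Trizol LS extraction, the Ambion WT expression kit and biotin labelling, per the labels' protocols. The labels' titles write miR-15b for the molecule that the design text calls miR-15b*, the name used here. The design text calls miR-107-mut1, miR-107-mut2 and the negative control non-physiological, and the sequences of the altered molecules were not given. Values were summarised by RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. The deposited values were read as log2 intensities, since RMA returns that scale and the values span its usual range. The log base is not stated, which is a limit on every fold given. All 54 arrays were used, and no values were altered for the tests described first.

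Of 33297 probe sets, 19460 had 1 gene symbol, 1754 several and 12083 none in the probe table. Those with 1 symbol were used (19429 matched the gene table by gene ID and 31 kept their symbol), and for 769 genes with more than 1 probe set the one with the highest mean was kept, which gave 18417 genes. The 7367 genes in the lowest 40% by mean over all arrays (below 5.26) were left out, so 11050 were tested. No array duplicated another (highest correlation 0.9947). Background probe values were not given, so signal over background was not analysed here, and the number of arrays limits the precision.

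Linear models were fitted in limma 3.58.1 (R 4.3.3, data.table, version 1.17.8) with moderated t-tests and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. IP and lysate arrays were fitted apart, 27 arrays and 9 groups each, with every transfection tested against the negative control. Contrasts were made of miR-103 with miR-107 against miR-16 with miR-195, of miR-107 against each altered molecule, and in the IP of miR-103 against miR-107 and miR-16 against miR-195. A fit of all 54 arrays gave the control IP against its lysate and 3 interaction terms. The IP arrays had a mean of 3.63 and the lysates 7.13, so the fractions appear to have been normalized apart. The test of control IP against lysate chosen beforehand carries that offset, and cyclic loess and, chosen after seeing the data, joint quantile normalization are given beside it. Interaction terms cancel an additive offset but not a difference in scale.

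Gene lists were written before the data were examined. They held known targets of miR-15/16/195, of miR-103/107 and of miR-320, genes of the G1 to S step, DNA replication, mitosis, replication-dependent histones, Argonaute and microRNA processing, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, interferon response, sterol synthesis, the unfolded protein response with ER chaperones, p53 targets, extracellular matrix, TGF-beta and activin signalling, lysosome, Alzheimer disease genes, neuronal, glial and haematopoietic markers, and actin cytoskeleton. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation and with fry. Genes named are the 10 largest rises and falls (5 for the altered molecules, miR-15b*, the pooled lysate contrast, the contrasts with the altered molecules and the interactions), or fewer from the top, among called genes whose replicates did not overlap, and members of the lists.

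Replicates with the same number carry a shared code in the labels' descriptions. Deviations from the group means correlated at a mean of 0.27 in the IP (-0.15 to 0.67) and 0.31 in the lysates (-0.47 to 0.95) between arrays of the same number, against -0.13 and -0.14 between other numbers, and 84 and 79 of 108 pairs were above 0.1. Every model was also fitted with a replicate block (interactions: IP minus lysate per culture, unpaired in their main fit). Similarity was set against 100 simulated draws of unchanged groups sharing the control. Alternatives were no filter, a filter of the lowest 60%, cyclic loess, eBayes with trend and robust settings and only the arrays compared. Others were array quality weights, the mean of 3 controls (negative control, miR-320 and miR-15b*), each array left out, and other splits.

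The models were tested on simulated independent genes, 200 of 11050 changed, built on the miR-107 comparison. In the IP 4.5%, 47.8% and 89.6% of changes of 0.5, 1 and 2 were recovered, and 7.8% of calls fell on unchanged genes, above the nominal 5%. In the lysate the shares were 47%, 89.6%, 100% and 6%. A shifted list was called in the IP and lysate (adjusted p = 4.1e-22 and 1.2e-46), and 0 of 21 others were. Correlated lists were not tested. Seed sites were not analysed here, since no transcript sequences were given. Figures used matplotlib 3.10.9 (Python 3.11.15).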

Results

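The series measured RNA bound to Argonaute, the protein that carries microRNAs to their target messages, in H4 cells, a human line with a glioneuronal phenotype. Cells were transfected with 1 of 9 small RNAs and harvested after 48 h. Members of the miR-15/107 group (miR-16, miR-195, miR-103 and miR-107) were set beside miR-320, miR-15b* (an antisense control, per the labels), the altered molecules miR-107-mut1 and miR-107-mut2, and a negative control RNA. From each culture the labels list an anti-Argonaute immunoprecipitate (IP) and the total lysate, with 3 biological replicates per condition, which gave 54 arrays in 18 groups. The IP arrays had means of 3.61 to 3.65 and the lysate arrays 7.11 to 7.16 on the log2 scale. Replicates of a group correlated at 0.803 to 0.964 across genes in the IP and at 0.894 to 0.991 in the lysates. The small number of arrays limits the precision. Levels below are mean log2 values ± SD (n = 3), log2 fold changes are given ± SE, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over 11050 genes. The replicates of every gene named from the largest changes did not overlap between the groups compared. List tests used camera with a preset correlation of 0.01.

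The first comparison asked which RNAs stood out in the control IP against the control lysate. As deposited, the control IP was lower for nearly every gene, with LMAN1, a cargo receptor of the secretory pathway, at 3.00 ± 0.47 in the IP and 11.70 ± 0.16 in the lysate, and the long noncoding RNA MALAT1 lower by a log2 change of -8.59 ± 0.56. The precursor genes of miR-182 and miR-99b were higher, MIR182 by 1.37 ± 0.21 (2.59-fold, adjusted p = 7.3e-08) and MIR99B by 0.73 ± 0.30 (adjusted p = 0.021). In all, 2 genes were higher and 11036 lower. The IP and lysate values lie 4.2 apart in the median (a shift of -4.2 before and 0.03 after cyclic loess), so these folds carry the offset between the fractions. After loess 4281 genes were higher and 4111 lower, and MIR182 (5.50 ± 0.21, adjusted p = 3.1e-24), MBP, which encodes myelin basic protein (5.34 ± 0.73), MIR99B (5.02 ± 0.26) and ZFP36, a decay factor for AU-rich messages (4.96 ± 0.33), were higher in the IP, while LMAN1 (-4.40 ± 0.39), MALAT1 (-4.29 ± 0.57) and SKAP2 (-4.13 ± 0.38) were lower. These genes after loess were chosen after their values were seen. Of 28 DNA replication genes, 1 was higher and 19 were lower after loess (list median -1.01, adjusted p = 0.0021 after loess, adjusted p = 0.0061 as deposited, and adjusted p = 0.97 with an estimated correlation). On the deposited values camera also called neuronal markers (adjusted p = 0.0061, and adjusted p = 0.68 with an estimated correlation), histones (adjusted p = 0.0061), p53 targets (adjusted p = 0.034, 0.081 with the replicate block) and the unfolded protein response (adjusted p = 0.036, 0.22 with the block) as lying above the other genes. The median and mean of these 4 lists were below 0 while the test pointed upward, and 0 of the 5 calls remained with an estimated correlation. After loess these 4 were at adjusted p = 0.19, 0.61, 0.61 and 0.19, and 6 further lists lay below the other genes. They were mitosis and ribosomal protein genes (adjusted p = 0.0024 each), Argonaute and microRNA processing (adjusted p = 0.011), and interferon, lysosome and oxidative phosphorylation genes (adjusted p = 0.028 each). As deposited these 6 passed no threshold (adjusted p = 0.97 with an estimated correlation).

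In the lysate of cells given miR-103, RAB27B, a GTPase of vesicle secretion, was at 9.64 ± 0.30 against 6.36 ± 0.07 in control lysate, a 9.73-fold rise (log2 3.28 ± 0.27, adjusted p = 1.9e-08). CEMIP2, a cell surface hyaluronidase, rose 8.38-fold, the chemokine gene CXCL14 8.12-fold and FBXO32, a muscle ubiquitin ligase, 6.17-fold. Among the falls were CBLN2, a synaptic organiser (7.99-fold lower), the histone chaperone ASF1B (7.68-fold lower, log2 -2.94 ± 0.22), the Polycomb-associated PHF19 (7.17-fold lower), DTL and TK1. Of 23 mitosis genes 22 fell, and 26 of 28 DNA replication genes fell (list medians -1.98 and -1.62, adjusted p = 4.8e-27 and 4.3e-33). Adjusted over the list alone 22 and 27 fell. Both calls held at adjusted p = 0.0069 with an estimated correlation. Of 33 replication-dependent histone genes 29 fell (31 adjusted over the list alone, median -1.05, adjusted p = 2e-23, and adjusted p = 0.071 with an estimated correlation). G1 to S genes had 1 rise and 11 falls among 22, the same counts when adjusted over the list alone (adjusted p = 2.7e-06). Known targets of miR-103/107 had 9 falls and 0 rises among 24 (1 rise and 9 falls adjusted over the list alone, adjusted p = 0.001), among them the calcium channel subunit gene CACNA2D1 (-1.99 ± 0.44), DICER1, which processes microRNA precursors (-1.81 ± 0.50), CDK6 (-1.57 ± 0.16), the β-secretase gene BACE1 (-0.83 ± 0.10, adjusted p = 4e-06) and the progranulin gene GRN (-0.69 ± 0.18, adjusted p = 0.011). AGO1, an Argonaute, fell by 1.33 ± 0.09 (adjusted p = 2.1e-09), and its list of Argonaute and microRNA processing genes had 5 falls among 28, 5 adjusted over the list alone (adjusted p = 0.0027, and adjusted p = 0.25 with an estimated correlation). Matrix genes rose, 12 of 34 and 12 adjusted over the list alone (adjusted p = 1.1e-06, and adjusted p = 0.25 with an estimated correlation). Of 50 ribosomal protein genes 3 fell, 0 adjusted over the list alone (median -0.14, adjusted p = 0.00041, and adjusted p = 0.24 with an estimated correlation). In all 1906 genes changed, 925 higher and 981 lower (1462 and 1372 with the block). Without control replicate 2 there were 1182, with only the arrays compared 1229 and with array weights 5589. Replicate 2 of the miR-103 lysate stood apart from the other lysates.

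For miR-107 the lysate pattern named many of these genes. RAB27B was at 10.22 ± 0.19, a 14.5-fold rise (log2 3.86 ± 0.27, adjusted p = 2.3e-09), CEMIP2 rose 10.7-fold and CXCL14 9.74-fold. ASF1B fell to 8.12 ± 0.11 from 11.34 ± 0.15 (9.35-fold lower, adjusted p = 2.3e-09), CBLN2 was 7.89-fold lower, PHF19 7.25-fold lower, the thymidine kinase gene TK1 6.87-fold lower and the mitotic kinase gene PLK1 6.16-fold lower. DNA replication genes fell in 27 of 28 cases (28 adjusted over the list alone, median -1.56, adjusted p = 5.7e-36), including the helicase subunit gene MCM7 (-1.93 ± 0.14). Mitosis genes fell in 21 of 23 cases (22 adjusted over the list alone, median -1.85, adjusted p = 2.5e-27), including CCNB1 (-2.24 ± 0.16), and histone genes in 30 of 33 (30 adjusted over the list alone, median -1.23, adjusted p = 2.8e-27, and adjusted p = 0.045 with an estimated correlation). Among 22 G1 to S genes CDK6 (-1.28 ± 0.16) was 1 of 10 falls and CCND1 (0.95) the 1 rise, against 2 rises and 13 falls adjusted over the list alone (adjusted p = 3.7e-05). The list of miR-103/107 targets had 7 falls and 1 rise among 24 (9 and 2 adjusted over the list alone, adjusted p = 0.0055), with BACE1 at -0.83 ± 0.10 and GRN at -0.77 ± 0.18. Matrix genes rose in 12 of 34 cases (15 adjusted over the list alone, adjusted p = 4.2e-10, and adjusted p = 0.15 with an estimated correlation), led by the matricellular genes CCN2 (2.46 ± 0.30), CCN1 (2.24 ± 0.37) and THBS1 (1.81 ± 0.16). TGF-beta and activin genes had 5 rises among 24 (5 rises and 1 fall adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.15 with an estimated correlation), and ribosomal protein genes 4 falls among 50, 4 adjusted over the list alone (adjusted p = 4.4e-05, and adjusted p = 0.15 with an estimated correlation). The total was 1642 genes, 719 higher and 923 lower. It was 3006 without the arrays that stand apart (chosen after seeing the data), 3012 with only the arrays compared and 5144 with array weights.

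With miR-16 the largest rise in the lysate was that of the cytokine gene IL6, from 6.61 ± 0.62 to 10.43 ± 1.01 (14.1-fold, log2 3.82 ± 0.75, adjusted p = 0.00085). CCN1 rose 11.6-fold, the transcription factor gene TFAP2C 8.99-fold, CCN2 8.19-fold and THBS1 7.30-fold (log2 2.87 ± 0.16, adjusted p = 1.3e-10). Falls were led by TDO2, a tryptophan-degrading enzyme (7.38-fold lower), the cadherin gene CDH10 (7.29-fold lower) and PRR11 (7.22-fold lower), and took in KIF20A, a kinesin of cell division (6.78-fold lower, adjusted p = 1e-06), and the cyclin gene CCNB2 (6.53-fold lower). All 23 mitosis genes fell, and 23 adjusted over the list alone (median -2.14, adjusted p = 1.5e-33), as did 26 of 28 DNA replication genes, 26 adjusted over the list alone (median -1.20, adjusted p = 4.8e-28), and 30 of 33 histone genes, 31 adjusted over the list alone (adjusted p = 5.1e-24, and adjusted p = 0.053 with an estimated correlation). G1 to S genes had 10 falls and 0 rises among 22 (13 falls and 1 rise adjusted over the list alone, adjusted p = 2.9e-06). Known targets of miR-15, miR-16 and miR-195 had 8 falls and 2 rises among 31 (13 and 4 adjusted over the list alone, adjusted p = 0.0016), with PHF19 at -2.39 ± 0.22 and WEE1, a kinase that holds back mitosis, at -0.99 ± 0.14, while JUN rose by 1.48 ± 0.22. The miR-103/107 target list had 6 falls among 24 (7 falls and 1 rise adjusted over the list alone, adjusted p = 0.037, and adjusted p = 0.053 with an estimated correlation), with BACE1 at -0.71 ± 0.10. Matrix genes had 12 rises among 34, 13 adjusted over the list alone (adjusted p = 2.9e-06, and adjusted p = 0.26 with an estimated correlation). Actin cytoskeleton genes had 12 rises and 1 fall among 38, 14 and 3 adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.24 with an estimated correlation). Of 21 p53 targets 7 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.04, and adjusted p = 0.26 with an estimated correlation). Of 32 lysosome genes 4 rose and 1 fell, 6 and 1 adjusted over the list alone (adjusted p = 0.037, and adjusted p = 0.5 with an estimated correlation). Ribosomal protein genes had 13 falls among 50, 15 adjusted over the list alone (adjusted p = 6.2e-08, and adjusted p = 0.053 with an estimated correlation). Argonaute and microRNA processing genes had 6 falls and 1 rise among 28, 7 and 1 adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.24 with an estimated correlation). There were 1879 genes changed, 1056 higher and 823 lower, 1169 without control replicate 2 and 1248 without control replicate 3. There were 616 with only the arrays compared and 7376 with array weights. Replicate 2 of the miR-16 lysate stood apart from the other lysates.

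Cells given miR-195 had IL6 at 10.73 ± 0.66 in the lysate, a 17.4-fold rise (log2 4.12 ± 0.75, adjusted p = 4e-04), with CCN1 11.7-fold, TFAP2C 8.33-fold and THBS1 7.74-fold higher. CDH10 was 6.54-fold lower, AOAH, a lipopolysaccharide-degrading enzyme, 6.46-fold lower and KIF20A 6.13-fold lower. Falls took in 23 of 23 mitosis genes (23 adjusted over the list alone, median -1.96, adjusted p = 3.4e-33), 25 of 28 DNA replication genes (28 adjusted over the list alone, median -1.20, adjusted p = 4.5e-28) and 29 of 33 histone genes (31 adjusted over the list alone, adjusted p = 1.4e-25, and adjusted p = 0.067 with an estimated correlation). G1 to S genes had 11 falls and 1 rise among 22, 12 and 1 adjusted over the list alone (adjusted p = 0.00018, and adjusted p = 0.067 with an estimated correlation). Targets of miR-15, miR-16 and miR-195 had 7 falls and 3 rises among 31, the same counts adjusted over the list alone (adjusted p = 0.044, 0.06 with the replicate block, 0.067 after loess, and adjusted p = 0.067 with an estimated correlation). Matrix genes had 14 rises among 34, 15 adjusted over the list alone (adjusted p = 1.8e-09, and adjusted p = 0.17 with an estimated correlation). Actin genes had 14 rises among 38, 14 with 1 fall adjusted over the list alone (adjusted p = 0.00017, and adjusted p = 0.067 with an estimated correlation). Of 21 p53 targets 7 rose, 7 adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.23 with an estimated correlation), and of 50 ribosomal protein genes 9 fell, 10 adjusted over the list alone (adjusted p = 3.2e-07, and adjusted p = 0.067 with an estimated correlation). Lysosome genes had 4 rises and 1 fall among 32, the same adjusted over the list alone (adjusted p = 0.044, and adjusted p = 0.51 with an estimated correlation). BACE1 was at -0.77 ± 0.10 (adjusted p = 1.3e-05). The count was 1552 genes, 754 higher and 798 lower, and 1030 without miR-195 replicate 2. It was 2924 without the arrays that stand apart and 5963 with array weights.

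**Figure D1:**
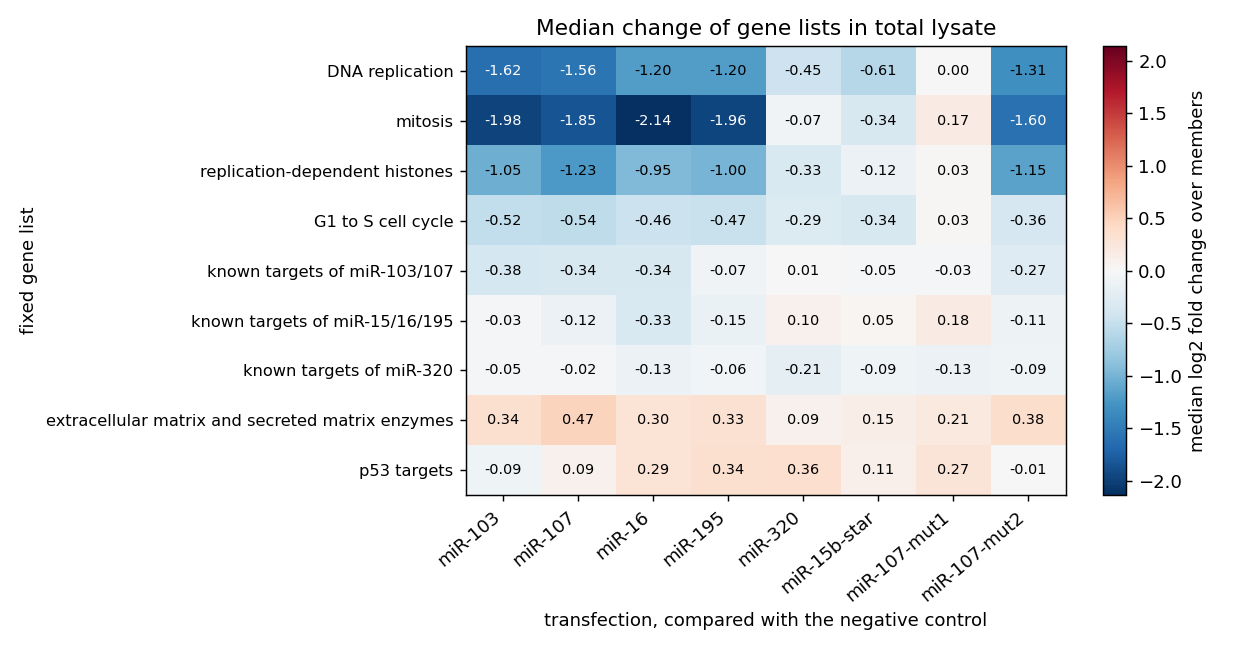
Heat map of the median log2 fold change against the negative control in total lysate for 9 gene lists (vertical) and 8 transfections (horizontal), with blue below 0 and red above 0. Mitosis genes have medians of -2.14, -1.96, -1.98 and -1.85 with miR-16, miR-195, miR-103 and miR-107 and of 0.17 with miR-107-mut1.

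The miR-320 lysate differed from control in fewer genes. ITGA6, an integrin subunit gene, rose from 8.01 ± 0.04 to 9.75 ± 0.16 (3.34-fold, log2 1.74 ± 0.43, adjusted p = 0.025), TMOD1, which caps actin filaments, rose 2.86-fold and the metalloprotease gene ADAM12 2.81-fold (adjusted p = 0.00045). CBLN2 was 6.26-fold lower (log2 -2.65 ± 0.23, adjusted p = 1.6e-06), the complement gene C3 4.06-fold and CDH10 4.05-fold. CBLN2 and CDH10 fell in all 8 lysates. Known targets of miR-320 had 2 falls and 1 rise among 15, 4 and 1 adjusted over the list alone (median -0.21, adjusted p = 0.0065, and adjusted p = 0.27 with an estimated correlation). These were VDAC1, a mitochondrial channel (-0.69 ± 0.11), ITGB3 (-0.69 ± 0.14) and the β-catenin gene CTNNB1 (0.74 ± 0.13), and CTNNB1 also rose with the 7 other transfections, by 0.53 (miR-15b*) to 0.87 (miR-107-mut1). DNA replication genes had 5 falls among 28, 16 adjusted over the list alone (median -0.45, adjusted p = 4.9e-16, and adjusted p = 0.18 with an estimated correlation). Among 22 G1 to S genes 4 fell, 5 adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 0.27 with an estimated correlation). Of 33 histone genes 1 fell, 2 adjusted over the list alone (adjusted p = 1.5e-07, and adjusted p = 0.57 with an estimated correlation), and of 34 matrix genes 1 rose, 1 adjusted over the list alone (adjusted p = 0.01, and adjusted p = 0.65 with an estimated correlation). In all 327 genes changed, 161 higher and 166 lower, and 671 with the replicate block. It was 996 without the arrays that stand apart and 2367 with array weights. It was 139 and 178 without control replicates 2 and 3, and 185, 217 and 202 without miR-320 replicates 1, 2 and 3.

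In the miR-15b* lysate WNT7B, a Wnt ligand gene, rose from 7.70 ± 0.40 to 9.85 ± 0.49 (4.42-fold, adjusted p = 2.4e-05), FBXO32 rose 3.63-fold and the gene of transcription factor JUN 2.86-fold. TDO2 was 9.16-fold lower (log2 -3.20 ± 0.54, adjusted p = 0.00046), CBLN2 8.14-fold lower and CDH10 7-fold lower. DNA replication genes had 14 falls among 28, 22 adjusted over the list alone (median -0.61, adjusted p = 4.1e-14, and adjusted p = 0.14 with an estimated correlation), and mitosis genes 2 falls among 23, 4 adjusted over the list alone (adjusted p = 1.2e-05, and adjusted p = 0.41 with an estimated correlation). G1 to S genes had 5 falls among 22, 7 adjusted over the list alone, with CCND2, a D-type cyclin gene, at -1.24 ± 0.21 (adjusted p = 1.2e-05, and adjusted p = 0.11 with an estimated correlation). Histone genes had 1 fall among 33, 0 adjusted over the list alone (adjusted p = 0.047, 0.069 with the replicate block, 0.097 after loess, and adjusted p = 0.82 with an estimated correlation). Interferon response genes had 3 falls among 26, 7 adjusted over the list alone (adjusted p = 0.00011, and adjusted p = 0.34 with an estimated correlation). In total 833 genes changed, 387 higher and 446 lower, 1509 with the replicate block, 386 without control replicate 2 and 488 without control replicate 3. It was 1299 without the arrays that stand apart, 50 with only the arrays compared and 5236 with array weights. Replicate 2 of this lysate stood apart from the other lysates.

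In the lysate of miR-107-mut1 FAIM2, which inhibits Fas-mediated death, was at 10.25 ± 0.27 against 7.79 ± 0.21 (5.51-fold, log2 2.46 ± 0.17, adjusted p = 2.8e-09), CXCL14 rose 5.03-fold and the transglutaminase gene TGM2 4.88-fold. DEPTOR, an inhibitor of mTOR, was 7.15-fold lower (log2 -2.84 ± 0.24, adjusted p = 9.9e-08) and the ephrin receptor gene EPHA4 5.82-fold lower. Of 23 mitosis genes 0 changed by limma, 0 adjusted over the list alone (median 0.17), beside 2123 of all genes at an unadjusted p under 0.05. Ribosomal protein genes had 11 falls among 50, 16 adjusted over the list alone (median -0.22, adjusted p = 4.1e-09, and adjusted p = 0.088 with an estimated correlation), and matrix genes 7 rises among 34, 8 adjusted over the list alone (adjusted p = 6.7e-05, and adjusted p = 0.53 with an estimated correlation). Interferon response genes had 4 rises among 26, 5 adjusted over the list alone, with MX2 at 1.09 and OAS3 at 0.61 ± 0.10 (adjusted p = 0.0027, and adjusted p = 0.41 with an estimated correlation). Of 11 neuronal markers 4 rose, 2 after loess and 4 adjusted over the list alone, among them MAP2 (0.68) (adjusted p = 0.02, 0.11 after loess, and adjusted p = 0.091 with an estimated correlation). Sterol synthesis genes had 3 falls among 18, 4 adjusted over the list alone, with SREBF2 at -0.81 ± 0.12 (adjusted p = 0.01, and adjusted p = 0.53 with an estimated correlation). Known targets of miR-15, miR-16 and miR-195 had 4 rises and 1 fall among 31, 5 and 3 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.088 with an estimated correlation), and p53 targets 3 rises among 21, 3 with 1 fall adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.41 with an estimated correlation). Altogether 969 genes changed, 368 higher and 601 lower, and 1591 with the replicate block. It was 2119 without the arrays that stand apart, 1555 with only the arrays compared and 4076 with array weights. Without miR-107-mut1 replicate 3 there were 576, and without control replicates 2 and 3 there were 628 and 641.

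After miR-107-mut2 the lysate had RAB27B at 10.03 ± 0.21 (12.8-fold higher, log2 3.67 ± 0.27, adjusted p = 1.2e-08), CEMIP2 10.2-fold and CXCL14 5.56-fold higher, PHF19 6.64-fold lower (adjusted p = 3.4e-08) and ASF1B 6.06-fold lower. Falls took in 26 of 28 DNA replication genes (27 adjusted over the list alone, median -1.31, adjusted p = 4.3e-31), 22 of 23 mitosis genes (22 adjusted over the list alone, median -1.60, adjusted p = 4.5e-26) and 29 of 33 histone genes (31 adjusted over the list alone, adjusted p = 1.6e-28), and these calls held with an estimated correlation (adjusted p = 0.013, 0.013 and 0.038). Known targets of miR-103/107 had 5 falls among 24, 7 adjusted over the list alone (adjusted p = 0.0053), with CDK6 at -1.15 ± 0.16 and BACE1 at -0.58 ± 0.10. G1 to S genes had 9 falls and 1 rise among 22, 10 and 1 adjusted over the list alone (adjusted p = 2.3e-05), and matrix genes 10 rises among 34, 13 adjusted over the list alone (adjusted p = 1.2e-06, and adjusted p = 0.29 with an estimated correlation). Argonaute and microRNA processing genes had 5 falls among 28, 6 adjusted over the list alone, with AGO1 at -1.08 ± 0.09 (adjusted p = 0.02, 0.09 after loess, and adjusted p = 0.38 with an estimated correlation). Of 50 ribosomal protein genes 7 fell, 7 adjusted over the list alone (adjusted p = 3.2e-07, and adjusted p = 0.076 with an estimated correlation). Glial markers, with 0 of 13 past the threshold in limma and 0 adjusted over the list alone, had a median of 0.23 (adjusted p = 0.03, 0.14 after loess, and adjusted p = 0.087 with an estimated correlation), beside 3093 of all genes at an unadjusted p under 0.05. In this lysate 1526 genes changed, 688 higher and 838 lower, and 2302 with the replicate block. It was 3462 without the arrays that stand apart, 2969 with only the arrays compared and 5162 with array weights.

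Direct contrasts of lysates followed. Between miR-103 with miR-107 and miR-16 with miR-195 (n = 6 against 6), TDO2 was higher by 2.06 ± 0.38 with the first pair (4.18-fold, adjusted p = 0.00085), the C-type lectin gene CLEC1A 3.73-fold and CXCL14 3.08-fold (log2 1.62 ± 0.10), while DKK1, a secreted Wnt antagonist, was 5.06-fold lower (log2 -2.34 ± 0.32), PSG4 4.13-fold lower and GPRC5A 3.75-fold lower. GRN was lower by a log2 change of -0.95 ± 0.13 (adjusted p = 3.2e-05). DNA replication genes had 13 falls among 28, 15 adjusted over the list alone, with MCM7 at -0.74 ± 0.10 (adjusted p = 1.7e-08, and adjusted p = 0.27 with an estimated correlation). Actin genes had 9 falls among 38, 11 with 1 rise adjusted over the list alone, with the myosin gene MYH9 at -1.06 ± 0.15 (adjusted p = 0.0026, and adjusted p = 0.27 with an estimated correlation). The contrast found 1109 genes, 394 higher and 715 lower, and 1736 with the replicate block. It was 1801 without the arrays that stand apart, 670 with only the arrays compared and 5914 with array weights. Of the 1109, 571 had every array of one pair above or below every array of the other.

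Against miR-107-mut1, the miR-107 lysate had RAB27B 13.4-fold higher (log2 3.74 ± 0.27, adjusted p = 3.4e-09), the complement receptor gene C3AR1 5.47-fold and the prostaglandin synthase gene PTGS2 5.21-fold higher. ASF1B was 9.81-fold lower (adjusted p = 2e-09), PHF19 9.13-fold lower and TK1 7.20-fold lower. Lower genes took in 27 of 28 for DNA replication (28 adjusted over the list alone, adjusted p = 1.6e-39), 21 of 23 for mitosis (22 adjusted over the list alone, adjusted p = 2.9e-33), 29 of 33 histones (31 adjusted over the list alone, adjusted p = 4.6e-31) and 10 of 22 for G1 to S (11 adjusted over the list alone, adjusted p = 8.3e-06). Targets of miR-103/107 had 9 falls and 2 rises among 24, 9 and 2 adjusted over the list alone (adjusted p = 0.0015), with CDK6 at -1.63 ± 0.16, BACE1 at -0.66 ± 0.10 (adjusted p = 7.7e-05) and GRN at -0.73 ± 0.18. Targets of miR-15, miR-16 and miR-195 had 8 falls and 1 rise among 31, 9 and 2 adjusted over the list alone (adjusted p = 0.0026), and these 6 lists held with an estimated correlation. Matrix genes had 6 rises and 1 fall among 34, 8 and 1 adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.51 with an estimated correlation), and lysosome genes 6 and 1 among 32, 8 and 1 adjusted over the list alone (adjusted p = 0.0037, and adjusted p = 0.39 with an estimated correlation). Of 42 nuclear genes of oxidative phosphorylation 2 rose, 2 adjusted over the list alone (adjusted p = 0.016, 0.067 after loess, and adjusted p = 0.39 with an estimated correlation). In sum 1488 genes differed, 769 higher and 719 lower (754 and 832 after loess). It was 2706 without the arrays that stand apart, 2353 with only the arrays compared and 4313 with array weights. Against miR-107-mut2 the miR-107 lysate differed in 9 genes, among them CXCL14 (0.81 ± 0.15, adjusted p = 0.033) and the semaphorin receptor gene NRP2 (0.70 ± 0.12, adjusted p = 0.031), higher, and the spermidine synthase gene SRM (-0.80 ± 0.16, adjusted p = 0.047) and the ion channel gene PIEZO1 (-0.80 ± 0.14, adjusted p = 0.031), lower. The count was 20 with the replicate block, 39 without the arrays that stand apart, 224 with array weights, and 0 with no filter and without any 1 of the 6 arrays. Camera called 7 lists with 0 members past the threshold, among them DNA replication (3 falls adjusted over the list alone, median -0.19, adjusted p = 6.6e-06, and adjusted p = 0.5 with an estimated correlation) and the unfolded protein response (0 adjusted over the list alone, adjusted p = 0.047, 0.28 after loess, and adjusted p = 0.53 with an estimated correlation). In limma 465 of all genes were at an unadjusted p under 0.05.

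In the Argonaute IP, miR-103 raised GRN, which encodes the secreted growth factor progranulin, from 7.63 ± 0.20 to 11.85 ± 0.55 (18.6-fold, log2 4.22 ± 0.48, adjusted p = 2e-05), while its level in the lysate fell. IER3IP1, an endoplasmic reticulum protein gene, rose 14-fold (log2 3.81 ± 0.39, adjusted p = 4.7e-06), and RBM14, GUCD1 and LDOC1 rose 4.57-fold, 4.16-fold and 4.15-fold. The cytidine deaminase gene APOBEC3B was 30.2-fold lower (log2 -4.92 ± 0.64, adjusted p = 0.00013), the nuclear import factor gene KPNA2 14.4-fold lower, MRGBP, of a histone acetyltransferase complex, 12.8-fold lower and SLC41A3 12.5-fold lower. Of 33 histone genes 14 fell, 24 adjusted over the list alone, with H3C2 at -2.92 ± 0.57 (median -1.43, adjusted p = 2.7e-19, and adjusted p = 0.21 with an estimated correlation), and of 50 ribosomal protein genes 10 fell, 4 after loess and 30 adjusted over the list alone (median -0.84, -0.34 after loess, adjusted p = 4.3e-15, and adjusted p = 0.21 with an estimated correlation). Mitosis genes had 3 falls among 23, 10 adjusted over the list alone, with CDC25C, a phosphatase that starts mitosis, at -2.77 ± 0.46 (adjusted p = 2.4e-07, and adjusted p = 0.21 with an estimated correlation). Oxidative phosphorylation genes had 0 of 42 past the threshold in limma and 0 adjusted over the list alone (median -0.54, adjusted p = 0.00044, and adjusted p = 0.6 with an estimated correlation), beside 1809 of all genes at an unadjusted p under 0.05. In total 26 genes rose and 198 fell, or 11.6% rises. After loess 97 rose and 344 fell (22%), with the median of all genes at -0.09 before and 0.02 after. The replicate block gave 850 genes, and there were 421 without the arrays that stand apart, 847 with only the arrays compared, 1263 with array weights and 395 against the mean of 3 controls. Leaving out 1 array gave 46 and 135 genes without control replicates 3 and 1, and 88, 82 and 106 without miR-103 replicates 1, 2 and 3.

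The miR-107 IP had GRN at 11.58 ± 0.29, a 15.5-fold rise (log2 3.95 ± 0.48, adjusted p = 6.1e-05), IER3IP1 10.3-fold and BOLA3, a gene of iron-sulphur cluster assembly, 3.38-fold higher. APOBEC3B was 19.5-fold lower, KPNA2 15.1-fold and SLC41A3 11.5-fold lower, MRGBP lower by a log2 change of -3.9 ± 0.41, and PABPC1, the cytoplasmic poly(A)-binding protein gene, 9.98-fold lower (log2 -3.32 ± 0.43, adjusted p = 0.00011). Histone genes had 14 falls among 33, 26 adjusted over the list alone (median -1.38, adjusted p = 5.1e-14, and adjusted p = 0.4 with an estimated correlation), and ribosomal protein genes 13 among 50, 4 after loess and 38 adjusted over the list alone (median -0.94, -0.26 after loess, adjusted p = 1.2e-11, and adjusted p = 0.4 with an estimated correlation). G1 to S genes had 7 falls among 22, 13 adjusted over the list alone (adjusted p = 5.5e-05, and adjusted p = 0.4 with an estimated correlation). Argonaute and microRNA processing genes had 4 falls among 28, 6 adjusted over the list alone, among them PABPC1, TNRC6A (-1.45) and CNOT7 (-1.55) (adjusted p = 0.0025, and adjusted p = 0.73 with an estimated correlation). Among all genes 24 rose and 399 fell (5.7% rises). After loess 141 rose and 379 fell (27.1%), with the median of all genes at -0.19 before and 0.01 after. With the replicate block 1950 genes changed, 989 without the arrays that stand apart, 1330 with only the arrays compared, 1217 with array weights and 884 against the mean of 3 controls. Without miR-107 replicates 2 and 3 there were 119 and 267, and without control replicates 1 and 3 there were 242 and 92.

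**Figure D2:**
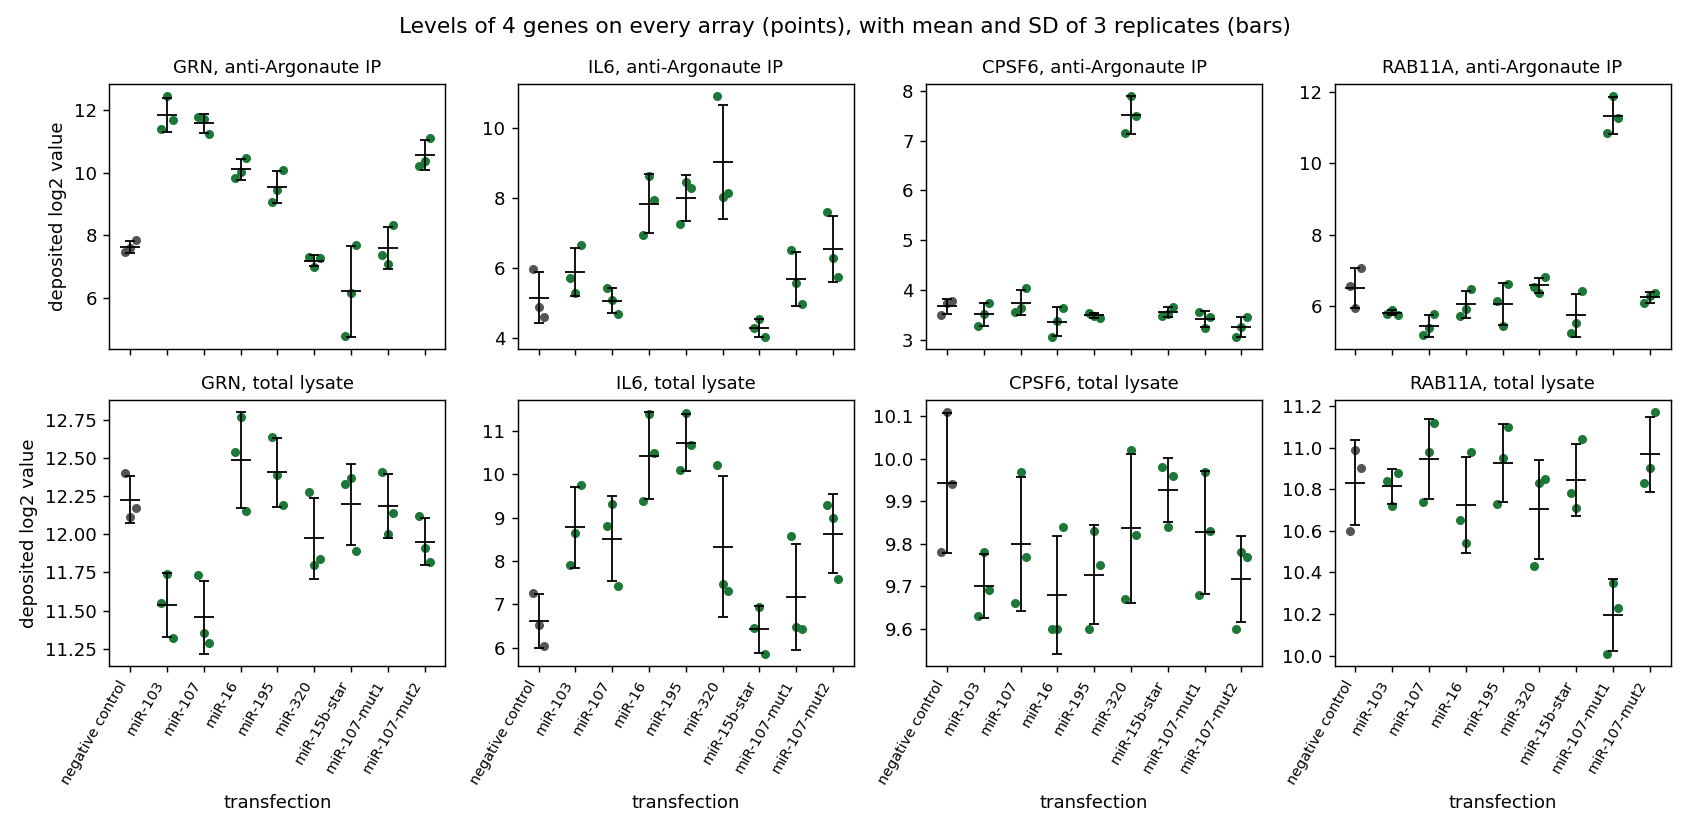
Deposited log2 values of GRN, IL6, CPSF6 and RAB11A for each transfection, with 1 point per array and bars for the mean and SD of 3, in the IP (top) and the lysate (bottom). The negative control is grey and the vertical ranges differ between panels, with GRN in the IP at 11.85 and 11.58 for miR-103 and miR-107 against 7.63 for the control.

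With miR-16 the IP gained IL6, from 5.15 ± 0.72 to 7.83 ± 0.84 (6.42-fold, log2 2.68 ± 0.63, adjusted p = 0.037, 0.097 against the mean of 3 controls), PCOLCE, an enhancer of collagen processing (5.59-fold, adjusted p = 0.0013), GRN (5.57-fold, adjusted p = 0.009) and the urokinase gene PLAU (4.86-fold). APOBEC3B was 16.8-fold lower, KPNA2 13.6-fold, MRGBP 13.1-fold and CKS1B, a cyclin-dependent kinase subunit gene, 9.24-fold lower. Histone genes had 11 falls among 33, 23 adjusted over the list alone (median -1.30, adjusted p = 4.3e-17, and adjusted p = 0.22 with an estimated correlation), and mitosis genes 5 among 23, 11 adjusted over the list alone (adjusted p = 3.2e-10, and adjusted p = 0.22 with an estimated correlation). Matrix genes had 2 rises among 34, THBS1 (1.98 ± 0.48) and CCN1 (1.56 ± 0.30), 2 adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.69 with an estimated correlation). Of the 139 genes changed 15 rose and 124 fell (10.8% rises), and after loess 59 rose and 194 fell (23.3%). The replicate block gave 586, and there were 277 without the arrays that stand apart, 722 with array weights and 216 against the mean of 3 controls. There were 50 and 33 genes without miR-16 replicates 1 and 2, and 66 and 19 without control replicates 1 and 3.

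The miR-195 IP had IL6 at 8.0 ± 0.65 (7.18-fold higher, log2 2.84 ± 0.63, adjusted p = 0.037, 0.089 against the mean of 3 controls), PLAU 4.95-fold and THBS1 4.85-fold higher, and APOBEC3B 15.6-fold, KPNA2 11.3-fold and MRGBP 10.5-fold lower. Histone genes had 9 falls among 33, 24 adjusted over the list alone (median -1.29, adjusted p = 3e-22, and adjusted p = 0.15 with an estimated correlation), and matrix genes 3 rises among 34, 4 adjusted over the list alone (adjusted p = 0.031, 0.05 with the replicate block, and adjusted p = 0.65 with an estimated correlation). In total 6 genes rose and 68 fell (8.1% rises), and after loess 46 rose and 147 fell (23.8%). The replicate block gave 396 genes, and there were 184 without the arrays that stand apart, 27 with only the arrays compared, 537 with array weights and 128 against the mean of 3 controls. Without miR-195 replicates 1 and 2 there were 36 and 21, and without control replicates 1, 2 and 3 there were 39, 45 and 16.

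miR-320 gave mostly rises in the IP. OSR2, a zinc finger transcription factor gene, rose to 10.79 ± 0.56 from 6.82 ± 0.56 (15.6-fold, log2 3.96 ± 0.51, adjusted p = 3.2e-05), IL6 14.7-fold, and CPSF6, a subunit of the cleavage factor for message 3' ends, from 3.67 ± 0.15 to 7.51 ± 0.37 (14.3-fold, log2 3.84 ± 0.20, adjusted p = 1.8e-11). LSM2, an RNA-binding ring subunit, rose 12.8-fold, the selenoprotein gene SELENOW 12.4-fold, the tubulin cofactor gene TBCA 11-fold and the dynein light chain gene DYNLRB1 10.1-fold. The precursor microRNA exporter gene XPO5 rose by 2.19 ± 0.30 (adjusted p = 7.2e-05) and the deadenylase subunit gene PAN3 by 1.23 ± 0.25 (adjusted p = 0.0048). MRGBP was 7.76-fold, SLC41A3 6.82-fold and TAF12, of the general transcription factor TFIID, 5.41-fold lower. Camera called DNA replication and histone genes as low, with 0 of 28 and 0 of 33 past the threshold in limma and 0 and 0 adjusted over the list alone (medians -0.26 and -0.34, both at adjusted p = 0.0011, and adjusted p = 0.98 with an estimated correlation), beside 804 of all genes at an unadjusted p under 0.05. Of 244 genes changed 234 rose and 10 fell, 373 changed with the replicate block, 395 after loess and 466 with array weights. Without control replicate 2 there were 148.

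The miR-15b* IP had LSM2 at 9.70 ± 1.00 (5.01-fold higher, log2 2.33 ± 0.38, adjusted p = 0.0056), MRGBP 10.3-fold, SLC41A3 9.5-fold and KPNA2 6.95-fold lower. Ribosomal protein genes had 0 of 50 past the threshold in limma, 1 rise and 8 falls adjusted over the list alone (median -0.57, 0 after loess, adjusted p = 0.00025, 0.74 after loess, and adjusted p = 0.9 with an estimated correlation), beside 1478 of all genes at an unadjusted p under 0.05. There was 1 rise and 23 falls (4.2% rises). After loess there were 27 rises and 48 falls (36%), with the median of all genes at -0.17 before and 0.01 after. The replicate block gave 521 genes, and there were 8 without the arrays that stand apart, 0 with only the arrays compared and 5 with array weights. Without miR-15b* replicates 1, 2 and 3 there were 8, 10 and 1407, and without control replicate 3 there were 6. Replicate 1 of this IP stood apart from the others.

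For miR-107-mut1 the IP rise was led by RAB11A, a GTPase of recycling endosomes, from 6.53 ± 0.56 to 11.34 ± 0.52 (28.1-fold, log2 4.81 ± 0.33, adjusted p = 6.5e-09). SNTB1, a syntrophin, rose 15.8-fold (log2 3.98 ± 0.34), the nucleoside transporter gene SLC29A1 12.7-fold and MIER2 8.73-fold. MRGBP was 6.86-fold, SLC41A3 6.41-fold and TAF12 5.67-fold lower. Ribosomal protein genes had 0 of 50 past the threshold in limma, 1 rise adjusted over the list alone (median -0.27, adjusted p = 0.0057, 0.051 after loess, and adjusted p = 0.96 with an estimated correlation), beside 545 of all genes at an unadjusted p under 0.05. Of 82 genes 64 rose and 18 fell, 151 changed with the replicate block, 169 after loess, 18 with only the arrays compared, 695 with array weights and 148 against the mean of 3 controls. Without miR-107-mut1 replicates 2 and 3 there were 49 and 48, and without control replicate 2 there were 43.

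The miR-107-mut2 IP had GRN at 10.57 ± 0.48 (7.69-fold higher, log2 2.94 ± 0.48, adjusted p = 0.0055), the protease gene PRSS23 3.02-fold and ITGA2 2.85-fold higher, and APOBEC3B 10.8-fold, KPNA2 9.23-fold and MRGBP 9.03-fold lower. Histone genes had 8 falls among 33, 22 adjusted over the list alone (median -1.29, adjusted p = 8.8e-33), and held at adjusted p = 0.05 with an estimated correlation, just under the threshold before rounding. Mitosis genes had 1 fall among 23, 9 adjusted over the list alone, with CDC25C at -2.33 ± 0.46 (adjusted p = 1.4e-13, and adjusted p = 0.064 with an estimated correlation). Of 38 genes 3 rose and 35 fell (7.9% rises), and after loess 25 rose and 95 fell (20.8%). The replicate block gave 156, and there were 73 without the arrays that stand apart, 184 with array weights and 88 against the mean of 3 controls. Without miR-107-mut2 replicates 1, 2 and 3 there were 16, 8 and 15, and without control replicates 1, 2 and 3 there were 21, 24 and 6. Camera called 2 of the lists in 0 of 28 comparisons, the Alzheimer disease genes (lowest adjusted p = 0.22) and haematopoietic markers (lowest adjusted p = 0.19).

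**Figure D3:**
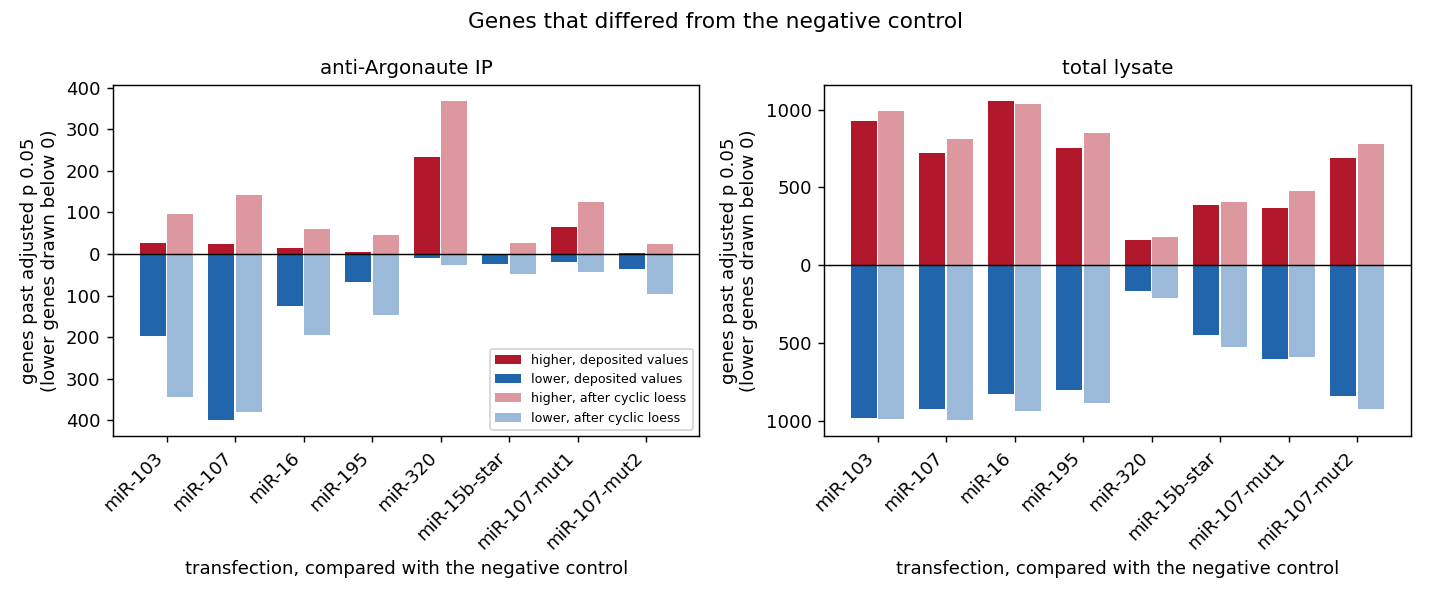
Number of genes higher (red, above 0) and lower (blue, drawn below 0) against the negative control for each of 8 transfections, in the IP (left) and the lysate (right), with dark bars for deposited values and pale bars after cyclic loess. In the IP miR-107 has 24 higher and 399 lower genes and miR-320 has 234 higher and 10 lower, and in the lysate miR-103 has 925 and 981.

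Within the IP, miR-103 with miR-107 was set against miR-16 with miR-195 (n = 6 against 6). IER3IP1 was at 9.5 ± 0.56 against 5.0 ± 0.32 (22.6-fold higher, log2 4.50 ± 0.27, adjusted p = 5.5e-10), the lysosomal nucleoside transporter gene SLC29A3 5.92-fold, GUCD1 5.54-fold, the mitochondrial aminotransferase gene GOT2 4.20-fold and GRN 3.71-fold higher (log2 1.89 ± 0.34, adjusted p = 0.0066). IL6 was 5.40-fold lower (log2 -2.43 ± 0.45, adjusted p = 0.0077), the claudin gene CLDN12 4.20-fold, PCOLCE 4-fold and DKK1 3.05-fold lower. Camera called p53 targets as low, with 0 of 21 past the threshold in limma and 4 falls adjusted over the list alone (median -0.39, adjusted p = 0.00044, and adjusted p = 0.94 with an estimated correlation), beside 702 of all genes at an unadjusted p under 0.05. There were 42 genes, 23 higher and 19 lower. There were 102 with the replicate block (39 higher and 63 lower), 102 after loess (59 higher and 43 lower) and 89 with array weights. Without miR-103 replicate 2, miR-107 replicate 3 and miR-16 replicate 2 there were 27, 26 and 27. Between miR-103 and miR-107 limma found 0 genes (364 at an unadjusted p under 0.05, and 0 with the block and after loess, which moved the median of all genes from 0.11 to -0.01). Between miR-16 and miR-195 it found 0 (125 at an unadjusted p under 0.05, 0 with the block, and 1 after loess).

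Against the IP of miR-107-mut1, that of miR-107 had GRN 15.8-fold (log2 3.98 ± 0.48, adjusted p = 1.4e-05), IER3IP1 12.3-fold and BOLA3 3.58-fold higher, and RAB11A 58.8-fold lower (log2 -5.88 ± 0.33, adjusted p = 1e-10), with the transcription factor gene JUNB 18.9-fold and SLC29A1 17.5-fold lower. Histone genes had 23 falls among 33, 30 adjusted over the list alone (median -1.58, adjusted p = 3.5e-17, and adjusted p = 0.43 with an estimated correlation), and G1 to S genes 7 among 22, 13 adjusted over the list alone (adjusted p = 7.8e-05, and adjusted p = 0.52 with an estimated correlation). There were 21 genes higher and 537 lower (3.8% higher). After loess there were 131 and 457 (22.3%), with the median of all genes at -0.21 before and 0.01 after. The replicate block gave 2012, and there were 1075 without the arrays that stand apart and 2731 with array weights. Without miR-107 replicates 2 and 3 there were 207 and 341, and without miR-107-mut1 replicates 1, 2 and 3 there were 957, 303 and 166. Against miR-107-mut2 the miR-107 IP differed in 4 genes, IER3IP1 (13.4-fold higher, log2 3.75 ± 0.39, adjusted p = 1.9e-05), SLC29A3 (4.93-fold), GOT2 (3.33-fold) and BOLA3 (2.98-fold), all higher. The count was 38 with the block (10 higher and 28 lower), 8 without the arrays that stand apart, 1 with only the arrays compared and 13 with array weights. It was 24 after loess (22 higher and 2 lower), which moved the median of all genes from -0.15 to 0. Without miR-107 replicate 1, miR-107-mut2 replicate 1 and miR-107-mut2 replicate 2 there were 2, 1 and 2. Ribosomal protein genes had 0 of 50 past the threshold in limma and 10 falls adjusted over the list alone (adjusted p = 6.1e-05, 0.65 after loess, and adjusted p = 0.89 with an estimated correlation), beside 991 of all genes at an unadjusted p under 0.05.

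Interaction terms tested whether IP and lysate changes differed. For miR-103 with miR-107, GRN gained 4.82 ± 0.46 in the IP relative to the lysate (28.2-fold, adjusted p = 6.4e-10), IER3IP1 3.86 ± 0.38 and GUCD1 2.83 ± 0.42, while MRGBP lost the most (-4.35 ± 0.37), followed by NPTN, a synaptic adhesion gene (-3.45 ± 0.38), and SLC41A3 (-3.39 ± 0.33). DNA replication genes had 11 of 28 positive terms, 19 adjusted over the list alone, led by RFC3 (2.08 ± 0.26) (median 0.94, adjusted p = 2.3e-20). Mitosis genes had 11 positive and 1 negative among 23, 13 and 2 adjusted over the list alone, led by the proliferation marker gene MKI67 (2.15 ± 0.30) (median 1.11, adjusted p = 2.4e-16), and both lists held with an estimated correlation (adjusted p = 0.023 and 0.036). Control IP medians were 4.25 for mitosis, 4.03 for DNA replication and 4.64 for all genes. Targets of miR-103/107 had 3 positive terms among 24, 3 adjusted over the list alone, GRN, CACNA2D1 (1.67) and CDK6 (0.84) (adjusted p = 0.0025, and adjusted p = 0.45 with an estimated correlation). Of 50 ribosomal protein genes 12 had negative terms, 1 after loess and 29 adjusted over the list alone (median -0.73, adjusted p = 3.9e-09, adjusted p = 0.92 after loess with a median of 0.06, and adjusted p = 0.45 with an estimated correlation). In total 187 terms were positive (25.9%) and 536 negative. Loess gave 315 and 309 (50.5%) and moved the median of all genes from -0.14 to 0.03. There were 434 without control IP replicate 3 and 478 without control lysate replicate 2, 1219 without the arrays that stand apart, 1856 with only the arrays compared and 2872 with array weights.

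For miR-16 with miR-195, CDH10 (2.43 ± 0.33), the topoisomerase gene TOP2A (2.18 ± 0.35) and CDH7 (2.14 ± 0.26) led the positive terms and MRGBP (-4.01 ± 0.37), SLC41A3 (-3.19 ± 0.33) and NPTN (-3.05 ± 0.38) the negative ones. Mitosis genes had 10 positive terms among 23, 12 adjusted over the list alone (median 1.09, adjusted p = 1.3e-21), and DNA replication genes 7 among 28, 12 adjusted over the list alone (median 0.60, adjusted p = 1.1e-16), both held with an estimated correlation (adjusted p = 0.018 and 0.033). Among 322 terms 93 were positive (28.9%) and 229 negative, and after loess 161 (46.5%) and 185. Without control IP replicate 3 and control lysate replicates 2 and 3 there were 188, 185 and 200. It was 560 without the arrays that stand apart, 2711 with array weights, 580 with no filter and 177 without the lowest 60%. For miR-320, OSR2 (4.01 ± 0.60), CPSF6 (3.95 ± 0.23) and DYNLRB1 (3.93 ± 0.43) led the positive terms and MRGBP (-3.51 ± 0.43), TAF12 (-2.82 ± 0.24) and SLC41A3 (-2.71 ± 0.39) the negative ones. Known targets of miR-320 had 1 positive term among 15, VDAC1, lost with the block and after loess. Adjusted over the list alone it was 1 (median 0.35, adjusted p = 0.024, 0.19 after loess, and 0.99 with an estimated correlation). In all 233 terms were positive and 19 negative (382 after loess, 693 with array weights).

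Genes higher in the IP and lower in the lysate of the same transfection numbered 21 of 234 for miR-320 (3.5 by chance from independent lists), among them DYNLRB1, 16 of 64 for miR-107-mut1 (3.5), among them RAB11A, 6 of 26 for miR-103 (2.3), namely GRN, GUCD1, IFRD2, BOLA3, NINJ1 and TMEM8B, and 3 of 24 for miR-107 (2). The miR-195 IP had 6 of its 6 higher genes higher in the lysate too (0.4 by chance), and miR-16 10 of 15 (1.4). IP and lysate came from the same cultures, so these lists share their chance values in part. Across 11050 genes, which are not independent replicates, the IP change correlated with the lysate change at 0.36 for miR-103, 0.26 for miR-107, 0.39 for miR-16, 0.40 for miR-195, 0.11 for miR-320, 0.17 for miR-15b*, 0.23 for miR-107-mut1 and 0.47 for miR-107-mut2.

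Changes against the shared control were also set against each other across genes. In the lysate miR-107 correlated at 0.94 with miR-107-mut2, 0.89 with miR-103, 0.83 with miR-195, 0.72 with miR-16 and 0.46 with miR-107-mut1. It was at 0.55 with miR-320 and 0.40 with miR-15b*. Simulated unchanged groups sharing a simulated control gave 0.43 (-0.51 to 0.93). The first 5 covariances were 0.164, 0.173, 0.151, 0.143 and 0.064 against 0.02 simulated, or 0.144, 0.153, 0.131, 0.122 and 0.044 above it. With the negative control for 1 member of a pair and miR-320 for the other, averaged over both orders, these r were 0.73, 0.70, 0.62, 0.53 and 0.11. The miR-16 and miR-103 lysates each hold an array that stands apart. In the IP miR-107 correlated at 0.88 with miR-103, 0.80 with miR-16, 0.80 with miR-195, 0.72 with miR-107-mut2, 0.70 with miR-15b*, 0.26 with miR-107-mut1 and 0.02 with miR-320. The simulated value was 0.50 (-0.08 to 0.83). Covariances above the simulated one were 0.2, 0.159, 0.144, 0.097, 0.119, 0.002 and -0.044. The higher genes of miR-107 in the lysate shared 531 with miR-107-mut2 (44.8 expected of independent lists) and 223 with miR-107-mut1 (23.9), and the lower ones 700 (70) and 203 (50.2). In the IP the genes lower with miR-107 shared 175 with miR-103 (7.1), 33 with miR-107-mut2 (1.3) and 16 with miR-107-mut1 (0.6), and the higher ones 10 (0.1), 2 and 0. The 3 controls cannot be split into 2 groups of at least 2, so part of any excess in the values with a shared control may come from that control.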

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

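Tests of value range, lysate level, recruitment and a shared shift were chosen only after the results were seen. The other splits of the arrays and the exchange of labels were planned.

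IP and lysate changes differed by interaction terms in limma. For miR-103 with miR-107 they did in 723 genes (GRN 4.82, IER3IP1 3.86, GUCD1 2.83, MRGBP -4.35, NPTN -3.45, SLC41A3 -3.39). For miR-16 with miR-195 it was 322 genes (CDH10 2.43, TOP2A 2.18, CDH7 2.14, MRGBP -4.01, SLC41A3 -3.19, NPTN -3.05). For miR-320 it was 252 genes (OSR2 4.01, CPSF6 3.95, DYNLRB1 3.93, MRGBP -3.51, TAF12 -2.82, SLC41A3 -2.71). For miR-103 with miR-107, 1 of 84 splits gave as many genes (highest other 46, and 36 among 26 parting as many pairs). For miR-16 with miR-195 it was 1 of 84 (highest other 187, and 6 among those parting as many). These splits mix transfections and cannot exclude chance.

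Of 13837 probe sets left out with no gene symbol or several, 4737 passed the filter. Against the control limma called 19 higher and 200 lower in the miR-107 IP, 4 and 55 with miR-16, and 41 and 5 with miR-320. Lysates gave 73 and 154, 111 and 137, and 10 and 23.

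MRGBP, SLC41A3, TAF12, NPTN, RNVU1-15, MRPL32 and RPL26L1 were higher in the negative control IP than in the IP of each of the 8 other transfections (7 genes, median 2.37). A higher level in the control lysate is argued against, since the lysate median of these genes was -8.29% of that in the IP. The value range of the arrays is argued against as the whole cause, since 85.6% of the IP median stayed after cyclic loess. Recruitment of these messages to Argonaute by the control molecule may explain them and stays open, with a lysate median of -0.2 (percentile 3.25 of random lists of genes with like levels). If it holds, the falls of these genes in the 8 comparisons come from the control and not from the microRNAs.

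Falls outnumbered rises in the IP of miR-16, miR-195, miR-103 and miR-107, and of miR-15b* and miR-107-mut2. The shared control was not tested as a cause. For the first 4, IP value range is argued against as the whole cause, since their highest share of rises was still 27.1% after loess. As part it stays open. Loess took rises from 8.26% to 24.4% of calls, but falls led by 718 before and 721 after. Lower lysate levels may contribute, since genes falling in the IP after loess had median lysate changes of -0.46, -0.51, -0.32 and -0.23, respectively.

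Replicates 2 of the miR-103, miR-16 and miR-15b* lysates lay apart from the other lysates, with COPS2, ZBTB41 and TERF1 lower by log2 changes of -2.72, -2.57 and -2.55. A shared technical shift may be the cause, since their deviations correlated at 0.92 to 0.95 across genes, against at most 0.64 in 15 other pairs of that number. An exchange of labels between the miR-16 and miR-103 arrays is argued against, since 2 of the 2 lay on the side of their own label. The miR-16 array scored 1.6 (own side 0.9 to 1.22, other side -1.01 to -0.81). The miR-103 array scored -0.45 (own side -1.01 to -0.81, other side 0.9 to 1.22). Both lay outside the range of their own side, so the condition set beforehand for dismissing an exchange was not fully met. Exchanges with other arrays were not tested. The labels give no processing batch for these arrays and no biological explanation was tested.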

How the results depend on the processing

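Leaving out the arrays that stand apart, joint quantile normalization, and loess for the gene lists were chosen only after the data were seen. Of 354 largest rises and falls picked by the rule over all comparisons, the direction and the side of the threshold stayed for 354 with the replicate block, 336 with no filter, 282 of 282 left with the lowest 60% out, 351 after loess, 348 with trend and robust settings, 319 with only the arrays compared, 352 with array weights, 352 without the arrays that stand apart, 178 of 194 with the mean of 3 controls, and 2287 of 2604 when each array was left out, where a group of 2 arrays borrows the spread of the others. The others passed no threshold but kept their direction, except ITGA2 with miR-16 in the IP, at -0.02 (adjusted p = 0.98) against the mean of 3 controls. The cause was not tested. Of 1514 calls of list members outside the control IP against lysate, 1504 stayed with the block and 1382 after loess, where 3 changed direction. Of 533 within it, 533 stayed with the block and 274 after loess, where 170 changed direction. Signal over background could not be read from the deposited values, so what it limits in the lower IP values is unknown.

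With the replicate block the IP counts became 850 (miR-103), 1950 (miR-107), 586 (miR-16), 396 (miR-195), 373 (miR-320), 521 (miR-15b*), 151 (miR-107-mut1), 156 (miR-107-mut2), 102 (pooled contrast), 2012 (miR-107 against miR-107-mut1) and 38 (against miR-107-mut2). In the lysates they became 671 (miR-320), 1509 (miR-15b*), 1591 (miR-107-mut1), 2302 (miR-107-mut2), 1736 (pooled) and 20 (miR-107 against miR-107-mut2), and the block moved no other count beyond 1.5 times. It ended the 5 list calls given in the report and added the unfolded protein response in the interaction of miR-103 with miR-107 (adjusted p = 0.034 in limma's camera), in the IP of miR-107 (0.041) and in the IP of miR-107 against miR-107-mut1 (0.029, with p53 targets at 0.03), glial markers with miR-103 in the IP (0.045) and the lysate (0.042), actin genes with miR-16 in the IP (0.032), lysosome genes with miR-107 in the lysate (0.037), and interferon genes, miR-320 targets and mitosis genes in the pooled lysate contrast (0.038 each). Without it these gained lists were at adjusted p = 0.15 to 0.79 with an estimated correlation. The block ended 10 list-member calls, among them VDAC1 and OAS1 in the miR-320 interaction. Blocked interactions gave 713, 316 and 238.

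Cyclic loess gave in the IP 441 (miR-103), 253 (miR-16), 193 (miR-195), 395 (miR-320), 75 (miR-15b*), 169 (miR-107-mut1), 120 (miR-107-mut2), 102 (pooled), 24 (miR-107 against miR-107-mut2), 1 (miR-16 against miR-195) and, for the miR-320 interaction, 382. The mean of 3 controls gave in the IP 395 (miR-103), 884 (miR-107), 216 (miR-16), 128 (miR-195), 148 (miR-107-mut1) and 88 (miR-107-mut2). No filter gave 580 for the miR-16 with miR-195 interaction, 0 for miR-107 against miR-107-mut2 in the lysate and 18398 for control IP against lysate, and the lowest 60% left out gave 177 and 7358 for the first and last of these, where more or fewer genes were tested.

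Array quality weights gave in the IP 1263, 1217, 722, 537, 466, 5, 695 and 184 for miR-103, miR-107, miR-16, miR-195, miR-320, miR-15b*, miR-107-mut1 and miR-107-mut2, and 89, 2731 and 13 for the pooled contrast and miR-107 against miR-107-mut1 and miR-107-mut2. In the same order they gave in the lysates 5589, 5144, 7376, 5963, 2367, 5236, 4076 and 5162, and 5914, 4313 and 224, with 2872, 2711 and 693 for the interactions of miR-103 with miR-107, miR-16 with miR-195 and miR-320. The cause was not tested.

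With only the arrays compared, the IP gave 847 (miR-103), 1330 (miR-107), 27 (miR-195), 0 (miR-15b*), 18 (miR-107-mut1) and 1 (miR-107 against miR-107-mut2), the lysates 1229 (miR-103), 3012 (miR-107), 616 (miR-16), 50 (miR-15b*), 1555 (miR-107-mut1), 2969 (miR-107-mut2), 670 (pooled) and 2353 (miR-107 against miR-107-mut1), and the interaction of miR-103 with miR-107 1856. Without the arrays that stand apart, the IP gave 421 (miR-103), 989 (miR-107), 277 (miR-16), 184 (miR-195), 8 (miR-15b*), 73 (miR-107-mut2), 1075 and 8 (miR-107 against miR-107-mut1 and miR-107-mut2), the lysates 3006 (miR-107), 2924 (miR-195), 996 (miR-320), 1299 (miR-15b*), 2119 (miR-107-mut1), 3462 (miR-107-mut2), 1801 (pooled), 2706 and 39 (miR-107 against miR-107-mut1 and miR-107-mut2), and the interactions 1219 (miR-103 with miR-107) and 560 (miR-16 with miR-195). The cause was not tested.

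Leaving out 1 array gave in the IP 46 to 165 (miR-103), 92 to 340 (miR-107), 19 to 124 (miR-16), 16 to 66 (miR-195), 148 to 228 (miR-320), 6 to 1407 (miR-15b*), 43 to 115 (miR-107-mut1), 6 to 24 (miR-107-mut2), 26 to 33 (pooled), 166 to 957 (miR-107 against miR-107-mut1), 1 to 5 (against miR-107-mut2), and 0 to 0 (miR-103 against miR-107, and miR-16 against miR-195). In the lysates it gave 1182 to 1655 (miR-103), 1210 to 1415 (miR-107), 1169 to 2453 (miR-16), 1030 to 1513 (miR-195), 139 to 256 (miR-320), 386 to 991 (miR-15b*), 576 to 771 (miR-107-mut1), 1032 to 1254 (miR-107-mut2), 805 to 1251 (pooled), 1009 to 1291 (miR-107 against miR-107-mut1) and 0 to 0 (against miR-107-mut2). Control IP against lysate had 11031 to 11036, and the interactions 434 to 768, 185 to 470 and 210 to 282.

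Of 616 list tests 183 passed the threshold, and 31 with an estimated correlation, 189 with the block, 152 with fry, 254 with no filter and 150 after loess. With miR-320 as the control of the second member, r in the IP was 0.69 (miR-103 with miR-107), 0.61 (miR-107 with miR-16), 0.11 (miR-107 with miR-107-mut1), 0.50 (miR-107 with miR-107-mut2) and 0.63 (miR-16 with miR-195), and in the lysates 0.70, 0.53, 0.11, 0.73 and 0.70, with -0.01 and -0.03 for miR-16 and miR-15b* with miR-107-mut1.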

Other observations

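The counts of genes set apart from all other groups and the control levels here were looked at after the data were seen.

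The IP of miR-320 had 178 genes higher than in each of the 8 other IP groups, led by OSR2, CPSF6, DYNLRB1, NRN1 and SELENOW, and that of miR-107-mut1 had 45, led by RAB11A, SLC29A1, SNTB1, FIZ1 and PLOD1. The IP of miR-103, miR-107, miR-16, miR-195, miR-15b* and miR-107-mut2 had 0 by limma. In lysates the negative control had 25 genes above every other group, led by CBLN2 and CDH10, and 53 below, among them FBXO32 and LOXL2. Their changes may come from the control. The miR-107-mut1 lysate had 20 higher, led by FAIM2, ELFN1 and the hedgehog receptor gene PTCH1 (smallest differences 1.35, 1.04 and 0.84), and 132 lower, led by the endosomal gene RAB5B (-1.43) and AP3D1 (-1.40). The miR-15b* lysate had 63 lower, led by ETNK2 and C5orf22 (each -1.47), and the miR-320 lysate 14 lower, led by TMEM255A (-1.10) and NXT2 (-0.83). These genes were chosen after their values were seen.

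After cyclic loess the 10 genes highest in the control IP against its lysate were MIR182 (5.50), MBP (5.34), MIR99B (5.02), ZFP36 (4.96), SERTAD3 (4.07), CHCHD10 (3.94), ZNRF2P1 (3.80), SOCS1 (3.77), CRYAB (3.74) and MIR21 (3.67), and joint quantile normalization gave 4.98, 5.06, 4.66, 4.46, 3.79, 3.65, 3.55, 3.55, 3.59 and 3.42. These genes too were chosen after their values were seen.

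Other splits of the arrays were tried for each comparison. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. For the IP of miR-103 the real value was 224, miR-107 423, miR-16 139, miR-195 74, miR-320 244 and miR-107-mut2 38, and for the lysates 1906, 1642, 1879, 1552, 327 and 1526, with 833 for miR-15b* and 969 for miR-107-mut1, each with 0 as the highest other. In the IP miR-15b* had 24 (highest other 1), miR-107-mut1 82 (2) and miR-107 against miR-107-mut1 558 (1). Against miR-107-mut2 miR-107 had 4 in the IP and 9 in the lysate, against miR-107-mut1 1488 in the lysate, and the miR-320 interaction 252, each with 0. In each of these 1 of the 10 splits gave as many. For miR-103 against miR-107 and miR-16 against miR-195 in the IP the real value was 0, with 1 and 0 as the highest other (10 of 10 splits as large). Other splits of a pooled contrast mix transfections and cannot exclude chance. Of 100 splits drawn from 462, 1 gave 42 genes in the IP (highest other 0). In the lysate 3 of 100 gave 1109 or more (highest other 2219). The 2 other splits as large put the apart arrays of miR-103 and miR-16 on the same side. In all 48 other splits did so (median 0), so this position alone does not give a large count. The cause was not tested. Without the arrays that stand apart the count was 1801.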
